A study of Populus ussuriensis with 12 samples.

How the data were processed

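Root RNA of WT and PuHSFA4a-overexpressing *Populus ussuriensis* was prepared with a TruSeq kit and sequenced on an Illumina instrument, per the labels' protocols. The deposited files, 1 per library and 12 in all, hold for each of 39602 genes a length, an FPKM value, a locus, a strand, a count and a normalized value. Of these genes, 39379 carry *P. trichocarpa* IDs of annotation v3.0 and 223 are named as new. Alignment with TopHat2 2.1.1 and counting with HTSeq 0.6.0 are named in the submitters' processing notes. The genome build, the strand setting and the handling of reads with several hits are not given in the sources used here. The *P. trichocarpa* gene set stands in for *P. ussuriensis*, so transgene reads fall on the *P. trichocarpa* gene they align to.

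The deposited counts are whole numbers and were treated as estimated counts of the authors, since they do not match the normalized column for every gene. For 64.6% to 65.9% of detected genes the count equals the value that the normalized column implies, and for 31.2% to 32.5% it is 1 above it. The implied values were within 0.02 of a whole number for 97.0% to 97.2% of detected genes. How these differences arose was not tested. The normalized column, the authors' signal value, lies near the count times 1 factor per library, from 0.875 to 1.18, and equals it only for the genes whose count equals the implied value. The factor is close to the inverse of a median-ratio size factor computed from the counts. The authors' FPKM values were not used for tests. Counts were used as deposited, as whole numbers, and the counts implied by the normalized column were tried as an alternative.

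Libraries were assigned to WT control, OE control, WT Zn and OE Zn from their titles. Numbers 1 to 3 within a group follow the order of deposit and do not pair libraries. The total count per library was 15594001 to 21206585, and 28609 to 29342 genes had at least 1 count. Replicate pairs differed by more than sampling noise, with a chi-square of 5.71 to 33.0 per degree of freedom, so no library was treated as a duplicate. The most abundant gene took 0.508% to 1.72% of the counts of a library.

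Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr, leaving 25871, and libraries were scaled by the trimmed mean of M-values (TMM). All 12 libraries entered 1 fit of 4 group means with 8 residual degrees of freedom, using the robust quasi-likelihood F-test and Benjamini-Hochberg adjustment with a threshold of 0.05. The 4 contrasts between groups and the interaction were tested. The biological coefficient of variation was 14.2%. CPM values use TMM-scaled library sizes, and SEs are the absolute log2 fold change divided by the square root of F. The scaling left the median log2 change of all genes at -0.004 to 0.008 in the 4 contrasts, and upper-quartile scaling moved it to at most 0.030.

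The design, the tests, the other settings to be tried and the naming rule were fixed before the data were examined. The rule names the HSFA4 loci and, per comparison, the 2 higher and 2 lower IDs with the largest absolute log2 fold change among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups. Other genes are named with the statement that they were chosen after their values were seen. The IDs of the HSFA4 loci were fixed from general knowledge, since the files pair no IDs with names. For the same reason 26 gene lists defined by words in gene descriptions, among them cell type markers, could not be filled and their tests were not run.

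The test was checked on simulated counts with the means, dispersions and library sizes of these libraries, for OE against WT on Zn with 25871 genes. It called 24 of 67 genes changed 1.5-fold, 43 of 67 changed 2-fold and 57 of 66 changed 4-fold, with 10 calls among 25671 unchanged genes. These counts were drawn independently for each gene, without joint shifts of genes within a library. The shares called may thus not carry over to the real comparison. There the HSFA4a locus was 7.82-fold higher in OE and did not pass. The settings tried beside these were DESeq2, limma-voom, median-ratio and upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, fits of the 2 compared groups alone (fixed beforehand for counts of calls, added later for the HSFA4a locus), a minimum absolute log2 fold change of 1, and leaving out each library in turn.

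Neighbouring genes were scanned for joint shifts on 19 chromosomes with 20299 genes of mean CPM above 3. Values were log2(CPM + 0.5), as deviations from the median of the 6 libraries in the same medium. A window of 21 genes was kept when its median lay more than 6 median absolute deviations from the median window of its library and more than 0.2 from 0. In 100 shuffles of the gene order 9.29 windows passed on average and 26 at most, against 809 in the real order. With the counts of 60 neighbouring genes thinned to 0.5 or 0.7 of their size in 1 library, the scan found 20 of 20 placed stretches at each size.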

Results

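Messenger RNA of roots was sequenced from in vitro plants of *Populus ussuriensis*, a poplar of northeast Asia. Wild-type plants (WT) and plants overexpressing PuHSFA4a (OE) were compared; HSFA4a is a heat shock transcription factor of class A. Plants of both genotypes were labelled as kept on control medium or on excess Zn, and roots were taken at an age of 21 days. The labels' protocol gives 1 week of pre-culture and then 2 weeks on medium with 1.2 mM zinc sulfate; this text stands with every sample, controls included, and was read as applying to the Zn groups only. Each of the 4 groups held 3 libraries, 12 in all. The total count per library ran from 15594001 to 21206585. Levels were expressed as CPM, the count scaled to the library total after TMM adjustment. A floor of 3 counts, for counting error only, corresponded to 0.141 to 0.192 CPM of the unadjusted totals. After low-count filtering 25871 genes were tested. The labels do not say whether the 3 libraries of a group came from separate plants or cultures, so p-values measure only the spread between these libraries. The files do not pair gene IDs with names, so genes are given by ID and no gene function is assigned to them.

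The overexpressed gene was examined first. The locus Potri.011G071700.v3.0 (chromosome 11, 6828550 to 6830854, minus strand; coordinates as in the deposited files) was taken as the HSFA4a locus from general knowledge of the *P. trichocarpa* annotation. Its level was 339 CPM ± 8.13 (SD, n = 3) in OE control and 257 CPM ± 16.3 (SD, n = 3) in OE Zn. It was 32.9 CPM ± 0.324 (SD, n = 3) in WT Zn and 110 CPM ± 65.8 (SD, n = 3) in the libraries labelled WT control. The lowest of the 6 OE libraries stood at 239 CPM and the highest WT library at 165 CPM. The 3 libraries labelled WT control differed from each other. The library labelled WT control 3 stood at 37.1 CPM, close to the WT Zn libraries. The libraries labelled WT control 1 and WT control 2 stood at 129 and 165 CPM, which was 3.47 and 4.44 times that level. These 2 libraries went partly against their label at this locus, and they are 2 of the 3 libraries behind each WT control value below. Across genes, the library labelled WT control 3 stood further apart. Its chi-square per degree of freedom was 15.7 against WT control 1 and 13.5 against WT control 2, where those 2 gave 7.69. Which of the 3 libraries best represents WT control was not tested.

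On Zn the locus was 7.82-fold higher in OE than in WT (log2 fold change 2.97, SE 0.41, edgeR quasi-likelihood adjusted p = 0.0575), with all 3 OE libraries above all 3 WT libraries. On control medium it was 3.08-fold higher in OE than in the libraries labelled WT control (log2 fold change 1.62, SE 0.38, edgeR adjusted p = 0.395), again without overlap. Neither passed the threshold in the fit of all 4 groups, in which the spread of the WT control libraries enters both. DESeq2 called the locus in both media (adjusted p = 0.0449 on control and 3.54e-08 on Zn), and limma-voom in neither (0.383 and 0.145). An exact two-sided permutation test of 3 against 3 libraries gave p = 0.1 in both media, the smallest p that design allows. In a fit of the 2 Zn groups alone, read for this locus only after the data were seen, the difference passed (edgeR adjusted p = 4.13e-06). The related loci Potri.004G062300.v3.0 and Potri.014G141400.v3.0, assigned on the same basis, differed less between genotypes. They stood at 38.1 CPM ± 2.93 and 15.2 CPM ± 0.66 in WT Zn and at 39.7 CPM ± 4.78 and 18.0 CPM ± 1.45 in OE Zn (SD, n = 3). On control medium they stood at 45.8 CPM ± 2.41 and 14.3 CPM ± 0.74 in WT and at 41.2 CPM ± 2.11 and 17.8 CPM ± 2.04 in OE (SD, n = 3). At Potri.014G141400.v3.0 each OE library, the lowest at 15.83 CPM, lay above each WT library, the highest at 15.78 CPM. Its edgeR unadjusted p was 0.011 on control and 0.040 on Zn, and the adjusted p 0.472 and 0.685.

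**Figure D1:**
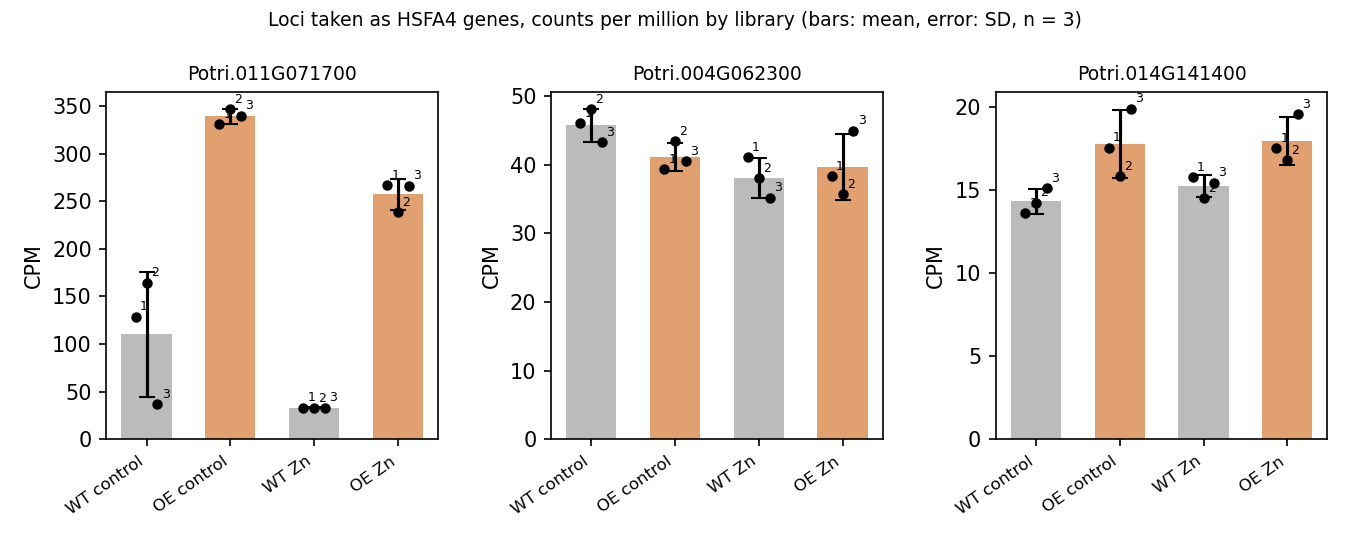
CPM of the 3 loci taken as HSFA4 genes, by group; bars are means, error bars SD, points the 3 libraries with their numbers. At Potri.011G071700.v3.0 all OE libraries lie at or above 239 CPM and all WT libraries at or below 165 CPM, with the libraries labelled WT control 1 and 2 far above WT control 3; the other 2 loci show no gap of that size.

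The comparison of OE with WT on control medium asks what the transgene changed without added Zn. No gene passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, and 2296 of 25871 genes had an unadjusted p under 0.05. Independent tests would give 1294 by chance, but genes can shift together, and 97 of the 2296 lay in the chromosome 13 stretch described below. The count was not taken for other splits of the libraries, so an excess was not tested. Limma-voom called 0 genes and DESeq2 called 81, of which 50 were higher and 31 lower in OE. With the libraries labelled WT control 1 and 2 left out, a choice made after seeing the data, edgeR called 11 genes, 8 of them higher in OE. WT control then rests on 1 library, which is assumed to vary like the other groups. That library had the largest chromosome 13 shift, described below, among the WT control libraries. In that fit the HSFA4a locus had a log2 fold change of 3.20. The 2 libraries left out were those that stood high at this same locus, so a larger difference there was fixed by the omission. With the library labelled WT control 3 left out, the only gene called was the HSFA4a locus (log2 fold change 1.21, edgeR adjusted p = 0.0014). WT control then rested on the 2 libraries that stood high at this locus.

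The comparison on Zn medium asks whether OE roots differed from WT roots under excess Zn. No gene passed in the edgeR quasi-likelihood test, 1845 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0575. Limma-voom called 0 genes and DESeq2 called 64, of which 27 were higher and 37 lower in OE. A fit of the 2 Zn groups alone called 4 genes, named here after their values were seen. The HSFA4a locus, Potri.T051700.v3.0 and Potri.010G089300.v3.0 were higher in OE and Potri.013G074500.v3.0 was lower. In the fit of all 4 groups the edgeR adjusted p was 0.311 for Potri.010G089300.v3.0 and 0.0575 for each of the others. On control medium Potri.010G089300.v3.0 went the other way, with a log2 fold change of -0.24. The HSFA4a locus (1.62), Potri.T051700.v3.0 (4.35) and Potri.013G074500.v3.0 (-0.74) kept their direction there. Potri.T051700.v3.0 (scaffold 48, 130858 to 151503) stood at 19.7 CPM ± 3.13 (SD, n = 3) in OE Zn and 0.359 CPM ± 0.341 in WT Zn. It overlaps Potri.T051900.v3.0 on the same strand, so reads of the 2 genes may not be told apart. Potri.010G089300.v3.0 (chromosome 10, 11298010 to 11300561) stood at 30.6 CPM ± 2.69 in OE Zn and 14.8 CPM ± 0.66 in WT Zn (SD, n = 3). Potri.013G074500.v3.0 (chromosome 13, 6385810 to 6388841) stood at 17.4 CPM ± 1.82 and 35.8 CPM ± 2.08 (SD, n = 3). Leaving out WT Zn 1 gave 19 calls and leaving out WT Zn 2 gave 1.

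Excess Zn changed many genes in WT roots. Of 25871 genes, 3970 were higher and 3760 lower on Zn than in the libraries labelled WT control, and 18141 did not pass (edgeR quasi-likelihood, adjusted p under 0.05). At an absolute log2 fold change of at least 1, 1221 genes were higher and 999 lower; at 3 or more, 161 were higher and 69 lower. Genes called higher held 18.5% ± 0.83 of all counts in the libraries labelled WT control and 28.9% ± 1.45 in WT Zn (SD, n = 3). Genes called lower held 25.2% ± 0.98 and 15.9% ± 0.39 (SD, n = 3). Both sets were chosen from these same WT libraries, which fixes the direction of both shifts and can enlarge them. The calls were spread over the genome. The share called ran from 23.02% of 995 genes on chromosome 13 to 33.79% of 941 genes on chromosome 15. Of 192 genes the authors' files name as new, 6 were higher, 27 lower and 159 did not pass.

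Among genes with a mean of at least 5 CPM and no overlap between the 2 groups, Potri.006G232600.v3.0 and Potri.001G255100.v3.0 rose most in WT, with Potri.006G048100.v3.0 close behind at a log2 fold change of 6.135. Potri.006G232600.v3.0 (chromosome 6, 24252200 to 24254376) went from 3.28 CPM ± 0.90 to 274 CPM ± 221 (SD, n = 3), a log2 fold change of 6.37 (SE 0.61, edgeR adjusted p = 0.000105). Potri.001G255100.v3.0 (chromosome 1, 26479372 to 26481456) went from 0.2302 CPM ± 0.1996 to 17.4 CPM ± 18.4 (SD, n = 3), a log2 fold change of 6.137 (SE 1.249, edgeR adjusted p = 0.00468). Both values leaned on WT Zn 3: without that library they were 5.48 and 4.76, and the ranking was not repeated. The call of Potri.001G255100.v3.0 was lost with limma-voom (adjusted p = 0.133) and without the libraries labelled WT control 1 and 2. The log2 fold change was then 11.3, but the 1 library left, WT control 3, had 0 counts of this gene. That value is thus set by the fit and is not a measured size. Potri.016G132100.v3.0 and Potri.008G136200.v3.0 fell most. Potri.016G132100.v3.0 (chromosome 16, 13549320 to 13549830) went from 8.23 CPM ± 1.23 to 0.0370 CPM ± 0.0325 (SD, n = 3). It had 471 counts in the 3 libraries labelled WT control and 2 counts in WT Zn, a 234-fold ratio of pooled counts with a 95% exact binomial interval of 64.5 to 1941, which covers counting error only and not the spread between libraries. The fitted log2 fold change ran from -7.06 to -8.06 when each library was left out. Potri.008G136200.v3.0 (chromosome 8, 9062110 to 9066851) went from 15.2 CPM ± 10.2 to 0.452 CPM ± 0.266 (SD, n = 3), a log2 fold change of -5.09 (SE 0.70, edgeR adjusted p = 0.000554), or -4.39 without the library labelled WT control 3. The HSFA4a locus itself had a log2 fold change of -1.74 in WT on Zn (SE 0.39, edgeR adjusted p = 0.00798). Without the libraries labelled WT control 1 and 2, which stood high at this locus, it was -0.17. A smaller fall was thus fixed by the omission.

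Excess Zn also changed OE roots. Of 25871 genes, 2203 were higher and 2210 lower on Zn, and 21458 did not pass (edgeR quasi-likelihood, adjusted p under 0.05). At an absolute log2 fold change of at least 1, 745 were higher and 628 lower. The genes called higher in WT held 19.996% ± 0.86 of all counts in OE control and 26.7% ± 1.06 in OE Zn (SD, n = 3). Those called lower in WT held 22.9% ± 1.26 and 16.8% ± 0.53 (SD, n = 3). Since the sets were chosen in WT, the sizes of these shifts cannot be compared between genotypes. Potri.006G179300.v3.0 and Potri.006G048100.v3.0 rose most in OE by the same rule. Potri.006G179300.v3.0 (chromosome 6, 19327697 to 19329076) went from 1.41 CPM ± 0.69 to 29.8 CPM ± 7.52 (SD, n = 3), a log2 fold change of 4.42 (SE 0.63, edgeR adjusted p = 0.00172), a call lost with limma-voom (4.47, adjusted p = 0.0596). Potri.006G048100.v3.0 (chromosome 6, 3435767 to 3437243) went from 0.913 CPM ± 0.332 to 17.9 CPM ± 13.1 (SD, n = 3), a log2 fold change of 4.30 (SE 1.00, edgeR adjusted p = 0.0161). That call was lost in 3 of 16 other settings: with limma-voom (adjusted p = 0.272), without OE control 2 (0.0686) and without OE Zn 2 (0.0501). The genes that fell most were again Potri.016G132100.v3.0, with 636 counts in OE control and 3 in OE Zn (233-fold, 95% exact binomial interval 79.5 to 1135, again for counting error only; fitted log2 fold change -7.69, from -7.14 without OE Zn 2 to -8.53 without OE Zn 3), and Potri.008G136200.v3.0, with a log2 fold change of -5.96 (SE 0.72, edgeR adjusted p = 0.000698). The number of calls depended on single libraries. It was 2200 without OE control 2, 2741 without OE control 3, 2689 without OE Zn 1 and 2742 without OE Zn 2.

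The Zn responses of the 2 genotypes overlapped. Of the genes called, 1769 were higher and 1774 lower in both, where 338 and 321 are expected for independent lists, and 3 were called in opposite directions. The 3543 shared calls fell to 1937 without OE control 2. The 2 comparisons share no libraries. Of the genes called in WT, 97.4% had the same sign in OE, and of those called in OE, 98.7% had the same sign in WT. Across the 25871 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.78 and a Spearman rho of 0.74; without the low-count filter r was 0.46 and rho 0.56. A further 4184 genes were called in WT only and 867 in OE only, which does not show that they responded differently. That difference was tested with the interaction of genotype and Zn. No gene passed in the edgeR quasi-likelihood test, 1627 had an unadjusted p under 0.05, limma-voom called 0 genes and DESeq2 called 5. No gene passed the OE-WT comparison in either medium with edgeR, so no edgeR call was shared between media. With DESeq2, 7 genes were called in both media with the same sign. The DESeq2 lists held 50 genes higher and 31 lower in OE on control, and 27 higher and 37 lower on Zn. The overlap expected for independent lists was not computed for them.

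**Figure D2:**
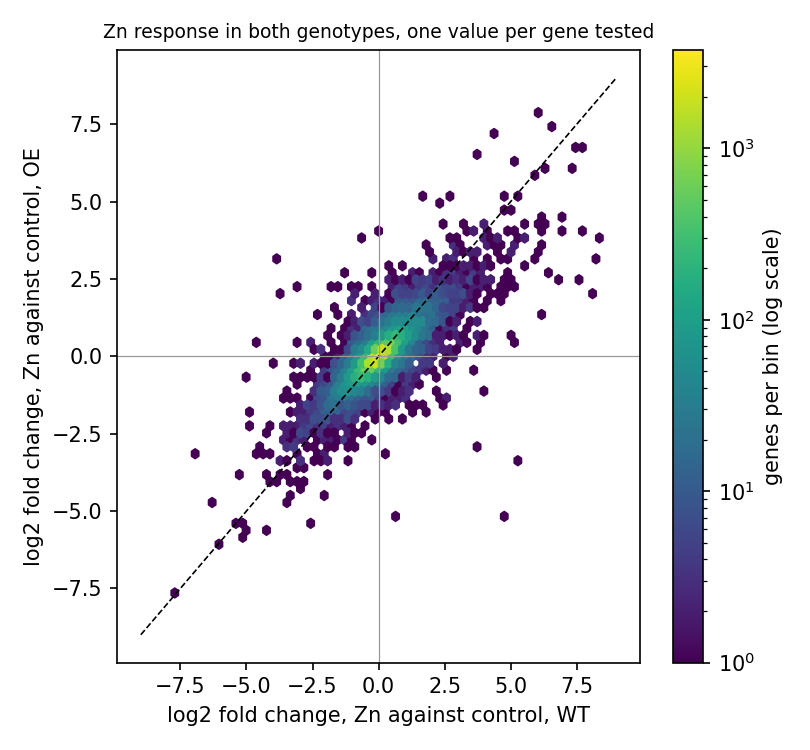
Log2 fold change on Zn against control in WT (horizontal axis) and OE (vertical axis) for 25871 genes; colour gives the number of genes per hexagon on a log scale and the dashed line marks equal change. Most changes have the same sign in both genotypes, with a Pearson r of 0.78 among these filtered genes (0.46 without the filter). The noise-corrected slope of OE on WT was 0.80 over 23776 of these genes, below that of the line, and was not tested. The ratio of the SD of the response in OE to that in WT was 0.816 (exact two-sided permutation p = 0.12).

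Positions on the chromosomes were scanned after the values were seen, in windows of 21 neighbouring genes. The scan kept 22 stretches over the 12 libraries, the longest of them at the start of chromosome 13. Of the 22, 8 lay there in OE control libraries, above the median of the 6 libraries on control medium, which the low WT control libraries pull down; the count of separate shifts is thus below 22. Elsewhere it kept, among others, 70 genes of chromosome 11 (1248837 to 3689169) in the library labelled WT control 3, with a median log2 deviation of -0.32 from the libraries in the same medium. Near the end of chromosome 13 it kept 34 genes in WT Zn 2 (median 0.079) and 30 in OE Zn 2 (median 0.13), and in the other direction 24 in OE control 2 (median -0.17). In the library labelled WT control 3, 211 genes at the start of chromosome 13, from 13425 to 2604237, had a median log2 ratio of -0.90 to the OE control libraries (interquartile range -1.08 to -0.67). In WT Zn 3 the same genes had a median log2 ratio of -0.89 to the OE Zn libraries (interquartile range -1.08 to -0.65). The libraries labelled WT control 1 and WT control 2 stood at -0.24 and -0.47. WT Zn 1 and WT Zn 2 stood at 0.015 and 0.034. The end at 2604237 is that of a window. A step placed gene by gene fell between the gene starts 2278510 and 2299361 in WT control 2, WT control 3 and WT Zn 3, each placed separately, and between 2268242 and 2272609 in WT control 1. The other 565 genes of chromosome 13 had medians from -0.005 to 0.028 in the 6 WT libraries. Of the 211 genes, 46.0% had an unadjusted p under 0.05 for OE against WT on control medium, against 8.57% of the 25660 genes elsewhere, and none of either set passed the adjusted threshold with edgeR. On Zn the shares were 0.948% and 7.18%, with a median log2 fold change of 0.23 in the stretch. For Zn in WT, 14.7% of the 211 genes were called, against 30.004% elsewhere, with a median log2 fold change of 0.30. For Zn in OE the shares were 4.27% and 17.2%, with a median of -0.010, so the lower share of calls was not limited to WT.

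**Figure D3:**
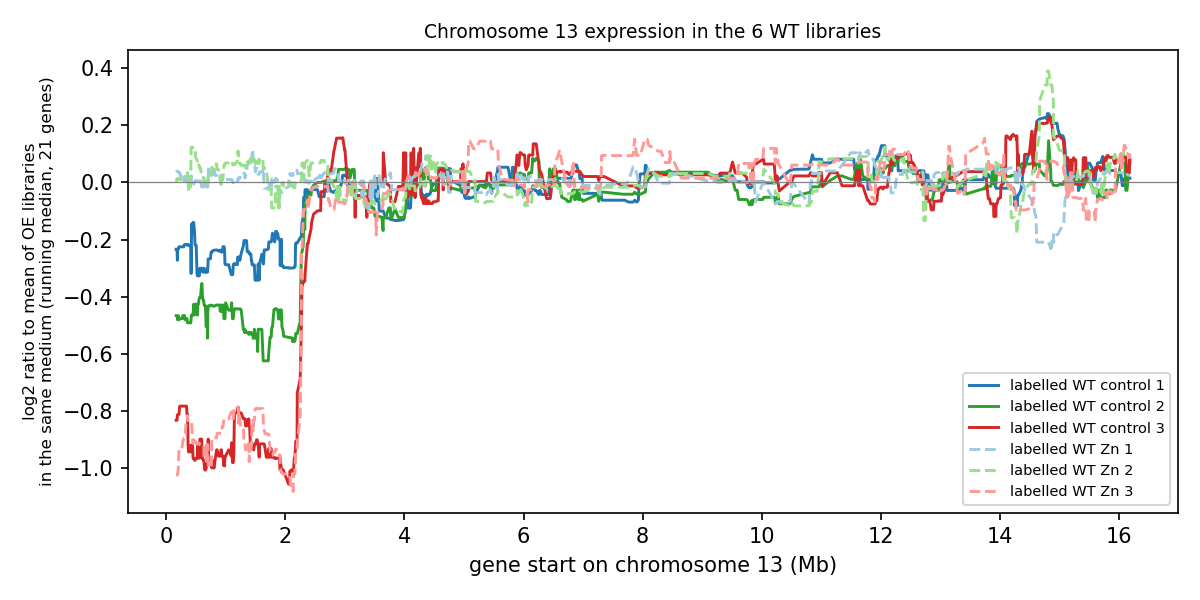
Running median over 21 genes of the log2 ratio of each WT library to the mean of the OE libraries in the same medium, along chromosome 13 (gene start in Mb). At the start of the chromosome the libraries labelled WT control 3 and WT Zn 3 lie near -0.90 and -0.89, WT control 1 and 2 lie at -0.24 and -0.47, and WT Zn 1 and 2 lie near 0.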

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

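Chosen after seeing the data were the response ratio, the omission of WT control 1 and 2 or of WT control 3 and WT Zn 3, the counts implied by the normalized values, the newer quasi-likelihood method, the omission of shifted stretches, and fits of 2 groups for the HSFA4a locus. The others, with fits of 2 groups for counts of calls, were planned. No paired analysis was possible because the labels give no replicate numbers. Tests of the 26 gene lists could not be run. Scaling did not change any call of the HSFA4a locus or move a count of calls by over 1.5 times. DESeq2 called 81, 64 and 5 genes for OE against WT on control, on Zn and for the interaction, where edgeR called 0, and 7 genes were shared between media; the HSFA4a locus then passed on control (1.62) and on Zn (2.97). Without a filter 10 genes were called for OE against WT on Zn and the correlation of Zn responses was 0.46; with at least 1 CPM in 3 libraries it was 0.82. A minimum log2 fold change of 1 left 2220 Zn calls in WT and 1373 in OE. Fits of 2 groups called 4 genes for OE against WT on Zn; the HSFA4a locus passed there (2.97) and for Zn in OE (-0.40) and no longer passed for Zn in WT (-1.75).

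Leaving out each library in turn gave 0 to 1 calls for OE against WT on control, 0 to 19 on Zn, 0 to 1 for the interaction, 6028 to 6692 for Zn in WT and 2200 to 4178 for Zn in OE. Shared Zn calls ran from 1937 to 3475, shared genotype calls from 0 to 1, and the correlation from 0.72 to 0.78. The log2 fold change of the HSFA4a locus ran from 1.21 to 2.03 for OE against WT on control, and passed without WT control 3. It ran from 2.94 to 3.02 on Zn and from 0.94 to 1.76 for the interaction, which passed without WT control 3. With WT control 1 and 2 left out, 11 genes were called for OE against WT on control, 1 on Zn and 4866 for Zn in WT; 1 genotype call was shared and the correlation was 0.61. The log2 fold change of the HSFA4a locus was then 3.20 on control, 2.97 on Zn and -0.17 for Zn in WT. WT control 1 and 2 stood high at this locus, so their omission fixed the direction in which its values against WT control moved. With WT control 3 and WT Zn 3 left out, the HSFA4a locus was the only gene called for OE against WT in each medium and for the interaction. It was thus the only call in both media. The correlation was 0.76, and the HSFA4a locus newly passed in 4 contrasts (1.21, 2.97, -0.40 and 1.76). Wherever WT control 3 was left out, WT control rested on WT control 1 and 2, which stood high at this locus. Its difference on control and its interaction in those fits depend on those levels. Counts implied by the normalized values gave a correlation of 0.77. The newer quasi-likelihood method called 13 genes for OE against WT on Zn, the HSFA4a locus among them (2.97), and 1 for the interaction. The cause of these moves was not tested, except that fewer libraries and fewer genes were tested where libraries or genes were left out. Of the genes named by the rule, Potri.016G132100.v3.0, Potri.008G136200.v3.0 and Potri.006G232600.v3.0 passed under every setting run, and Potri.001G255100.v3.0 lost its call in 2 of 17, Potri.006G048100.v3.0 in 3 of 16 and Potri.006G179300.v3.0 in 1 of 16. At the depth, spread and group size of these libraries a simulated 1.5-fold change was called in 35.8% of genes. The simulated genes were drawn independently, so that share may not hold for the real libraries. Depth was not varied.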

Other observations

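The tests in this part were chosen after the results were seen, except the counts of other splits for the Zn comparisons. Neighbouring genes called on Zn changed in the same direction more often than in shuffled gene orders. In WT, 1459 neighbouring pairs of tested genes changed in the same direction, where 200 shuffles gave 1146 on average and 1230 at most. In OE the count was 491, where shuffles gave 376 on average and 441 at most. Pairs that changed in opposite directions numbered 990 in WT and 320 in OE, where shuffles gave 1142 and 371 on average and 1090 and 310 at least. All called pairs together came to 2449 in WT, where shuffles gave 2426 at most, and to 811 in OE, within the 817 that shuffles reached. Of the 1459 same-direction pairs in WT, 53.5% lay on the same strand, against 50.5% of all neighbouring pairs. Potri.013G101000.v3.0 (chromosome 13, 11347121 to 11349338), singled out after its values were seen, had the highest mean CPM in WT Zn of the genes called higher there. It went from 871 CPM ± 457 in the libraries labelled WT control to 10876 CPM ± 6181 in WT Zn, and from 572 CPM ± 43.0 to 4807 CPM ± 2619 in OE (SD, n = 3).

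The WT libraries differed at the start of chromosome 13, and the genotype as labelled does not account for it, since WT Zn 2 had a median log2 ratio of 0.034 to OE. A bias by gene length or abundance is argued against too: genes elsewhere matched on both had a lowest median of 0.0046 in the libraries labelled WT control 3 and WT Zn 3. A candidate explanation is a loss of 1 copy of the stretch in some plants, which predicts a drop to about 50% that ends at a sharp edge. At the step placed in WT control 3, the median in WT Zn 3 rose by 1.04 from the 20 genes before to the 20 genes after it. Other causes of a lower level over neighbouring genes could give such a step and DNA was not measured, so the explanation stays open, as do the middle values of WT control 1 and 2.

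The first 5 scanned genes of chromosome 2 (4173 to 63718) stood at log2 ratios of 0.40, 0.44 and 0.55 in the libraries labelled WT control 1, 2 and 3 and 0.69 in WT Zn 3, against -0.04 and 0.015 in WT Zn 1 and 2. Each OE library set against the other 2 of its group ran from -0.024 to 0.028 on control and from -0.19 to 0.21 on Zn. These genes were picked after their values were seen and were not found by the scan of 21-gene windows.

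The HSFA4a locus was high in the libraries labelled WT control 1 and 2. A swap with an OE library is argued against, since the higher of the 2 reached 0.497 of the lowest OE control library and no OE library fell to a WT level. Reads taken from the HSFA4 relatives are argued against as well: the relatives together changed by 2.63 CPM where the locus gained 110 CPM. OE material mixed into these libraries stays open. The HSFA4a locus lay at 0.310 and 0.428 of the way from the other WT libraries to OE control. The 5 other genes that separate OE from the other WT libraries had medians of 0.226 and 0.218. They ran from 0.056 to 0.351 and from -0.006 to 0.567, too few and too spread to decide. The lowest in both libraries was Potri.T051700.v3.0, with means of 0.298 CPM in the other WT libraries and 7.81 CPM in OE control. That gene had 15 and 5 counts in WT control 1 and 2, and from 3.28 to 12.9 CPM in the OE control libraries. With so few counts and that spread, its position does not decide on mixing. The highest were Populus_trichocarpa_newGene_808 in WT control 1 and Potri.013G074500.v3.0 in WT control 2. A difference between the plants was not tested.

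The Zn response was smaller in OE than in WT, though not beyond what regrouping gives. The SD over genes of the log2 response, computed from pairs of contrasts with no shared library so that replicate noise drops out, was 0.59 in WT and 0.49 in OE, a ratio of 0.816. An exact two-sided permutation of the genotype labels within each medium, over 400 arrangements, gave p = 0.12. The ratio ran from 0.749 to 0.895 when each library was left out and was 0.880 without WT control 3 and WT Zn 3. The noise-corrected correlation of both responses was 0.98.

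For the Zn comparisons, the real split of 6 libraries gave 7730 calls in WT and 4413 in OE, 1 of 10 splits in each, and the highest other split gave 0 calls in both. Splits of 3 against 3 are too few for a share under 0.05. Each other split also put Zn and control libraries into both groups, so a Zn difference widened the spread there. That favours 0 calls, so the contrast with the real count adds little. For OE against WT edgeR called 0 genes in the real split and in the other splits, in both media, and 0 for the interaction in the real grouping and in the other regroupings. With a real count of 0 the 10 of 10 splits and 40 of 40 drawn regroupings counted as large are fixed in advance and decide nothing. DESeq2, which was not run on other splits, called 81 genes on control, 64 on Zn and 5 for the interaction. Unadjusted p under 0.05 were found for 2296, 1845 and 1627 genes with edgeR, and these were not counted in other splits either.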
